A study of Caenorhabditis elegans with 4 samples.

How the data were processed

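Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on late embryos of Caenorhabditis elegans strain OP398, in which a transgene expresses the homeodomain protein DVE-1 fused at its C terminus to GFP. Per the labels' protocols, worms were grown at 20 °C, crosslinked with 2% formaldehyde, lysed and sonicated, and chromatin was precipitated with an anti-GFP antibody; a part of each lysate was kept as input. The labels name 4 samples, which are 2 ChIP samples and 2 input samples with matching replicate numbers. No label says whether the replicates came from separate worm cultures, so the spread between them may be technical.

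The data analysed here are 3 peak lists, 1 for each ChIP replicate and 1 for the series as a whole, called the combined list below. Values for the input samples on their own were not analysed here. Per the file headers the coordinates are on WormBase build WS180, and per the deposited files the peaks were called with PeakSeq. Each deposited peak has a start, an end and a q-value as the authors' peak caller gave it, with no read count, enrichment or summit. The aligner, the q-value threshold, the use made of the input and the way in which the combined list was built are not given in the sources used here. The largest q-value was 0.000205 in the list of replicate 1, 0.000173 in that of replicate 2 and 0.000305 in the combined list. Because the files carry no read counts, the sequencing depth is unknown, and q-values were used only to rank peaks within a list or to compare how the same peak was scored in different lists. The smallest gap between neighbouring peaks was 200 bp in the combined list, 207 bp in replicate 1 and 205 bp in replicate 2.

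The gene table at hand was on another build, WBcel235, and no WS180 genome or annotation was used here. Coordinates were not converted between builds. The planned tests of positions relative to genes, of gene lists, of RNA genes and of sequence motifs had been made conditional on a matching build, and were therefore not run. For the same reason no peak is assigned to a gene, exon, intron or UTR, and peaks are named by coordinates, 1-based as in the deposited files. The rule for named peaks in that case, the 10 highest-ranked of the combined list, was set before the data were examined, as were the tests and alternatives other than those said below to have been chosen afterwards.

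Peaks were called shared when they overlapped by at least 1 bp. The observed overlap was set against 10000 circular shifts, in which one list was moved along each chromosome by a random distance, wrapping at its end. Overlap counts were checked against bedtools 2.31.1. The scores of peaks shared between replicates were compared as −log10 q, with 100000 resamples. Chromosome lengths were not in the files, so the span of each chromosome was taken as the largest peak end over the 3 lists; the 6 spans sum to 100246310 bp. The share of peaks on each chromosome was compared with its share of the span, and the share in the middle of 3 equal parts of each chromosome with 1 part in 3, by 2-sided exact binomial tests with Benjamini-Hochberg adjustment. These tests treat peaks as independent of each other. Shares have 95% Clopper-Pearson intervals, which cover counting error only.

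The alternatives were a 50% reciprocal overlap, midpoints within 200 bp, the better-ranked 50% of each list, either replicate's list in place of the combined list, only peaks found in both replicates, and peaks within 1000 bp of each other counted once. Spans from the combined list alone, and leaving out peaks under 50 bp, were added after the data were seen. Tests of X against autosomal peak width, of the X share of the 100 and 250 highest-ranked peaks and of rank classes, of left against right chromosome ends, of distances between peaks, and of chromosome shares between groups of peaks were also chosen after the data were seen. The procedures were tested on simulated data: of 100 pairs of independently drawn lists as long as the replicate lists, 3% fell under the 0.05 threshold of the permutation test of overlap, and an X density planted at 0.5 of the autosomes was recovered with a median ratio of 0.512 in 100 draws of 5000 peaks. The simulated peaks were placed at random along the chromosomes with the widths of replicate 1, and each pair had 200 shifts. Such peaks are not clustered, so the check does not cover clustering of the real peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.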

Results

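DVE-1 binding was mapped in late C. elegans embryos by ChIP-seq of a GFP fusion, in 2 ChIP replicates with 2 input samples. DVE-1 is a homeodomain protein of the SATB type, known for its part in the mitochondrial unfolded protein response. PeakSeq listed 1709 peaks in replicate 1, 2109 in replicate 2 and 4971 in the combined list. Peaks were short. Their median width was 310 bp (quartiles 242 and 431) in replicate 1, 368 bp (273 and 519) in replicate 2 and 319 bp (228 and 467) in the combined list. They covered 0.654%, 0.944% and 1.96% of the chromosome span, respectively. All peaks lay on the 6 nuclear chromosomes. Positions are given on WormBase build WS180; no annotation of that build was used, so the genes at these positions are not stated. The sequencing depth behind the peaks is unknown, and the input samples were not analysed on their own.

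The highest-ranked peak of the combined list lay on X at 424812–437987, with the authors' q-value of 1.76e-182. It was also the widest, at 13176 bp, and was a single peak in both replicates, ranked 11 in replicate 1 and 5 in replicate 2. Directly to its right, after a gap of 430 bp, lay the second-widest peak of the combined list, at X 438418–442662, with a width of 4245 bp and rank 341. This neighbour was also listed in replicate 1, at rank 634, but not in replicate 2. The second-ranked combined peak lay on IV at 14032371–14034889 and the third-ranked on II at 2525359–2526202, and each held the same rank, 2 and 3, in both replicates. Of the next peaks, 3 lay on the left part of IV, at 1785069–1785662 (rank 4), 2403235–2404009 (rank 5) and 3455217–3455925 (rank 8). These peaks were between 594 and 775 bp wide and ranked between 4 and 8 in each replicate. The others among the 10 best were X 16929332–16931950 (rank 6), II 12169301–12170075 (rank 7), I 7474093–7476159 (rank 9) and II 11633755–11636160 (rank 10). Those at ranks 6 and 10 were single peaks in the combined list but 2 peaks each in both replicates. All 10 were found in both replicates.

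**Figure D1:**
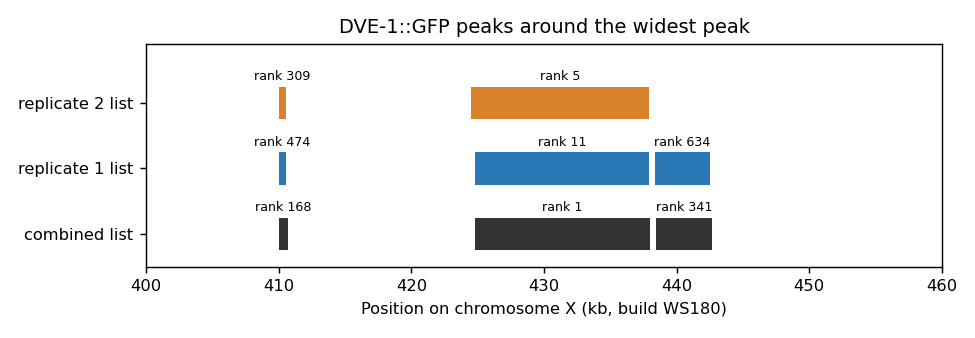
Peaks between 400 and 460 kb on chromosome X (horizontal axis, kb on build WS180) in the combined list and in each replicate list (rows); bars are drawn to scale and labelled with the peak's rank in its list. The 13176 bp peak appears as 1 peak in all 3 lists, and the 4245 bp neighbour is in the combined and replicate 1 lists.

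The first comparison asked how far the replicates found the same peaks. In replicate 1, 1287 of 1709 peaks overlapped a peak of replicate 2, which is 75.3% (95% interval 73.2 to 77.3). In replicate 2, 1278 of 2109 peaks overlapped a peak of replicate 1, which is 60.6% (58.5 to 62.7). Circular shifts of the lists gave means of 1.90% and 1.53%, with highest values of 17.8% and 14.7%. A random distance could be very short and leave the peaks of a chromosome almost in place. The highest values may come from such shifts, which was not examined. Both observed shares exceeded every one of the 10000 shifts (1-sided permutation p = 0.0001 for each, the smallest these shifts can give). The overlap depended on rank. The 100 best peaks of each replicate were all found in the other, with a lower limit of 96.4%. Of ranks 101 to 500, 98.0% were shared in replicate 1 and 94.8% in replicate 2, and of ranks 1001 to 1500, 58.2% and 48.8%. Among the lowest-ranked, from rank 1501 on, 46.9% of 209 peaks in replicate 1 and 29.9% of 609 in replicate 2 were shared.

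The shared peaks were also ranked alike in both replicates. Across 1275 pairs of overlapping peaks, −log10 q had a Spearman rho of 0.649 and a Pearson r of 0.902 (permutation p = 1e-05 for each, the smallest the resamples can give). These correlations are across peaks, which are not independent replicates. Without the 2 peaks farthest from the median, at I 15064008–15067642 and IV 14032578–14034580, rho was 0.647 and r was 0.856. Of the 100 best peaks of replicate 1, 72 were paired with one of the 100 best of replicate 2.

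The combined list was then set against the replicate lists. Of its 4971 peaks, 1261 (25.37%, 95% interval 24.2 to 26.6) overlapped a peak in both replicates, 375 (7.54%) only in replicate 1 and 777 (15.6%) only in replicate 2. The remaining 2558 (51.5%, 50.1 to 52.9) were in neither. Peaks in neither replicate were narrower, with a median of 257 bp against 459 bp for peaks in both, and lower in rank, with medians of 3601.5 and 664. All of the 100 best combined peaks and 149 of the next 150 were in both replicates, whereas 80.4% of ranks 501 to 1000, 31.5% of ranks 1001 to 2000 and 5.2% of ranks 2001 to 3000 were. The best-ranked combined peak found in neither replicate was II 6491642–6492119, at rank 772. In the other direction, 47 peaks of replicate 1 (2.75%) and 52 of replicate 2 (2.47%) were not in the combined list. One of these was the best-ranked peak of both replicates, at I 15064008–15067642 in replicate 1 (q-value 2.98e-125) and I 15064009–15067638 in replicate 2 (q-value 5.41e-186). The ribosomal RNA gene array is known to lie at the right end of chromosome I, but whether this peak lies in it was not checked. The next-best peak missing from the combined list ranked 626 in replicate 1 and 1200 in replicate 2. The combined list belongs to the same series and the way it was built is not given in the sources used here, so these shares carry no test.

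**Figure D2:**
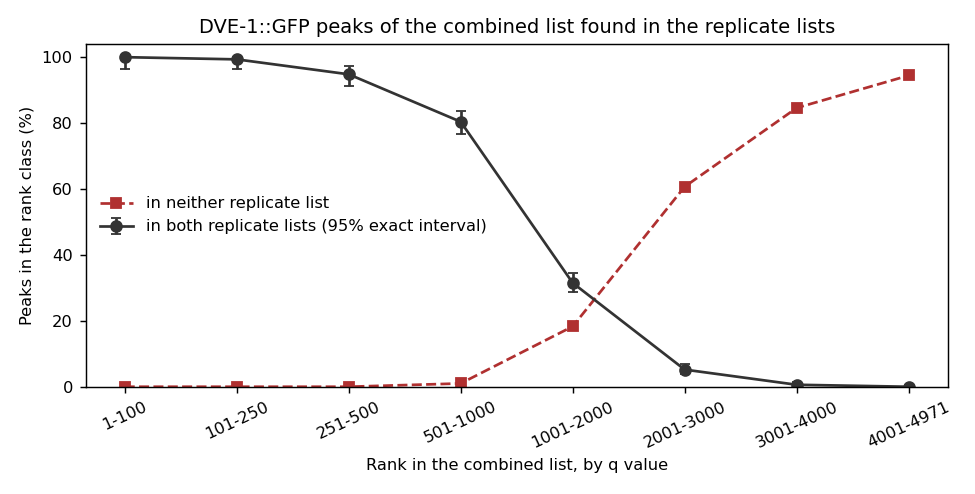
Share of combined-list peaks (vertical axis, %) in rank classes by q-value (horizontal axis) that overlapped a peak in both replicates (circles, with 95% exact binomial intervals) or in neither (squares). The share in both fell from 100% in ranks 1 to 100 to 31.5% in ranks 1001 to 2000, while the share in neither rose to 94.4% beyond rank 4000.

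Peak numbers were then compared between chromosomes. In the combined list chromosome III carried the most peaks for its span, with 1032 peaks or 75 per Mb, 1.51 times the number proportional to its span (exact binomial, adjusted p = 2.41e-41). Chromosome II had 927 peaks or 60.7 per Mb, 1.22 times that number (exact binomial, adjusted p = 1.62e-10). Chromosome V was lower, with 915 peaks or 43.7 per Mb, a ratio of 0.882 (exact binomial, adjusted p = 2.42e-05). The X chromosome had 454 peaks, or 25.6 per Mb, against 54.7 per Mb over the autosomes. The density on X was thus 0.468 of that on the autosomes (95% interval 0.424 to 0.516; exact binomial p = 2.12e-65), and it was 0.327 (0.267 to 0.396) in the list of replicate 1 and 0.419 (0.357 to 0.489) in that of replicate 2. Chromosomes II, III, V and X passed the test in the same direction in both replicate lists. Chromosomes I and IV did not. Chromosome I had 839 combined peaks, a ratio of 1.12 (exact binomial, adjusted p = 0.000392), but ratios of 0.895 and 0.946 in replicates 1 and 2 (exact binomial, adjusted p = 0.0873 and 0.378). Chromosome IV had 804 combined peaks, a ratio of 0.927 (exact binomial, adjusted p = 0.0176), and ratios of 1.003 and 0.967 in replicates 1 and 2 (exact binomial, adjusted p = 0.949 and 0.509).

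**Figure D3:**
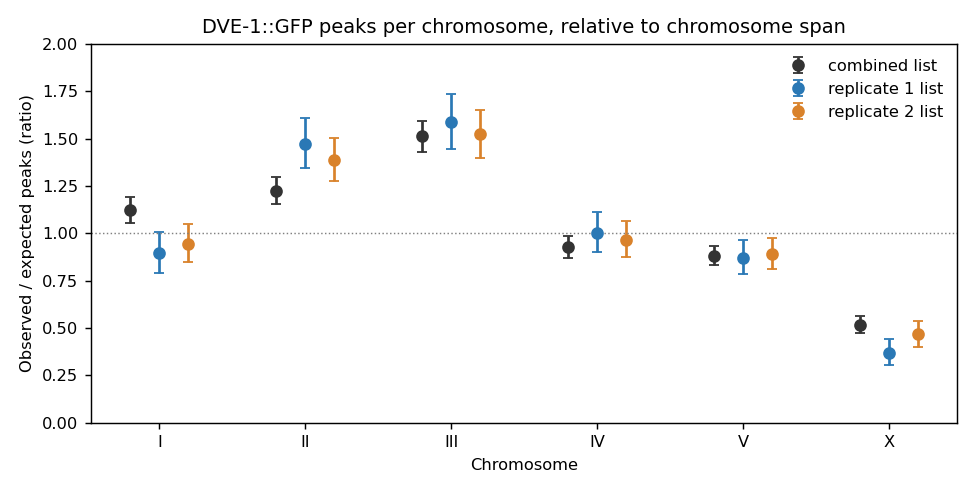
Ratio of observed peaks to the number proportional to chromosome span (vertical axis) for each chromosome (horizontal axis) in the combined and replicate lists; points are ratios, bars 95% exact binomial intervals, and the dotted line marks a ratio of 1. X lies below 1 in all 3 lists, and III and II lie above 1.

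In the combined list and in replicate 1, X held a larger share of the 100 best peaks than of the rest. Of the 100 best combined peaks, 16 lay on X (16%, 95% interval 9.43 to 24.7), against 8.99% of the rest and 17.7% of the span. The share among the 100 best was 15% in replicate 1, against 6.03% of the rest, and 13% in replicate 2, against 8.01% of the rest. The difference passed the 2-sided Fisher's exact test in the combined list (adjusted p = 0.0367 over 5 tests) and in replicate 1 (Fisher's exact test, adjusted p = 0.00618), and did not in replicate 2 (Fisher's exact test, adjusted p = 0.091); whether the replicates differ in this was not tested. In the combined list, the X share was 13.3% in ranks 101 to 250, 8.4% in ranks 251 to 500 and 6.2% in ranks 501 to 1000, and between 8.5% and 10.2% in the classes beyond rank 1000. The density ratio of X to the autosomes was 0.887 in ranks 1 to 100 (exact binomial, adjusted p = 0.793 over 8 rank classes) and 0.717 in ranks 101 to 250 (exact binomial, adjusted p = 0.226). Among the 250 best peaks, X held 14.4% in the combined list (10.3 to 19.4; exact binomial p = 0.185, adjusted p = 0.278 over 6 chromosomes), which did not pass the test. It held 10.8% in replicate 1 (7.24 to 15.3; exact binomial p = 0.00357, adjusted p = 0.0107) and 11.6% in replicate 2 (7.91 to 16.23; exact binomial p = 0.0101, adjusted p = 0.0302), both below its share of the span. In the 6 classes of the combined list beyond rank 250 the density ratio lay between 0.308 and 0.529, and each passed the exact binomial test. Peaks on X were also wider. Their median width was 401 bp against 312 bp on the autosomes in the combined list, 452.5 against 306 bp in replicate 1 and 489.5 against 358 bp in replicate 2 (permutation test, adjusted p = 0.0001 in each list, the smallest it can give). The tests of the 100 best peaks, of the 250 best, of the rank classes and of peak width were chosen after the data were seen.

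The last comparison asked whether peaks favoured or avoided the middle of 3 equal parts of each chromosome, and no chromosome passed the test in either direction. Boundaries of chromosome arms and centres were not used, so the result concerns equal parts only. On the autosomes 1553 of 4517 combined peaks, 34.4% (95% interval 33.0 to 35.8), lay in the middle of 3 equal parts of each chromosome, where an even spread would give 33.3% (exact binomial, adjusted p = 0.322 over 7 tests). On X the share was 31.1% (26.8 to 35.5; exact binomial, adjusted p = 0.447). It was lower in the list of replicate 1, at 24.1% or 27 peaks (16.53 to 33.1; exact binomial p = 0.0445, adjusted p = 0.311), and in that of replicate 2, at 28.7% (22.1 to 36.1; exact binomial p = 0.228, adjusted p = 0.377). Among X peaks found in both replicates it was 23.3% (15.1 to 33.4; exact binomial p = 0.0444, adjusted p = 0.311). Among the single autosomes the middle share ranged from 31.4% on III to 37.0% on II, and none passed the adjusted test, although II had an unadjusted exact p of 0.0195. The 95% intervals of the single autosomes ran from 28.6% at the lowest, on III, to 40.2% at the highest, on II. The autosomal middle share was 33.0% in the list of replicate 1 and 33.1% in that of replicate 2, on the other side of an even spread.

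**Figure D4:**
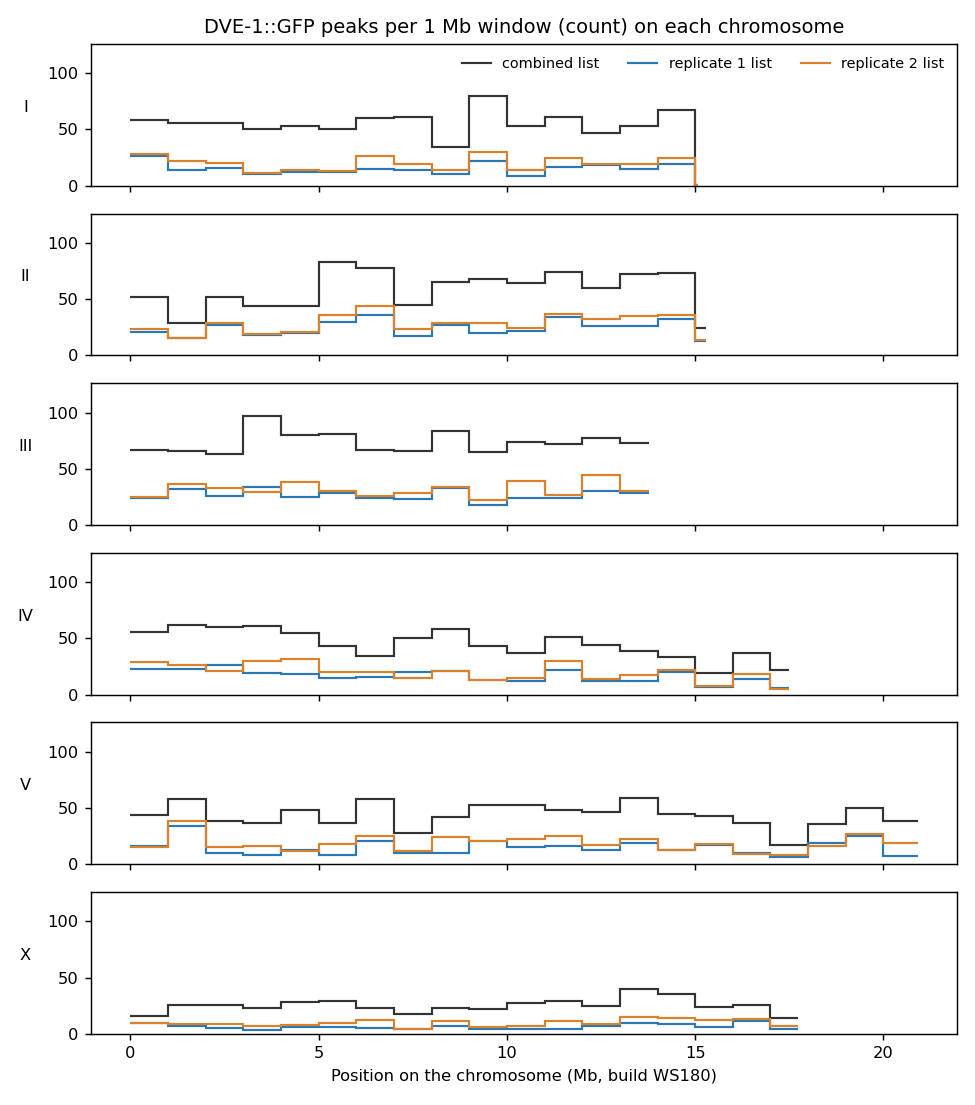
Number of peaks (vertical axis, count) in windows of 1 Mb along each chromosome (horizontal axis, Mb on build WS180) in the combined and replicate lists. In the combined list the windows on X lie lower than those on III; the last window of each chromosome is shorter than 1 Mb.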

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

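Spans from the combined list alone and leaving out peaks under 50 bp were chosen after the data were seen. Below, "without replicate 1" means that the list of replicate 2 took the place of the combined list, and "without replicate 2" that the list of replicate 1 did. The combined list was not rebuilt without a replicate. The overlap between replicates kept its direction and passed its test under every alternative run, with shares between 66.9% and 76.3% of replicate 1 and between 54.2% and 61.5% of replicate 2. Spearman's rho of shared peaks was 0.687 with a 50% reciprocal overlap and 0.668 with the better-ranked 50% of each list, against 0.649. The density ratio of X to the autosomes stayed between 0.327 and 0.506 over these alternatives, and the middle share passed its test in no alternative. The autosomal middle share nevertheless crossed 33.3%, from 34.4% to 33.1% without replicate 1, 33.0% without replicate 2 and 32.6% with only peaks in both replicates. So did that of I, from 34.6% to 32.6% without replicate 2 (34.3% without replicate 1) and 32.4% with only peaks in both replicates, that of V, from 35.96% to 33.1% without replicate 2 (36.2% without replicate 1), and that of IV, from 33.2% to 33.4% without replicate 2 (30.3% without replicate 1), 34.3% with peaks within 1000 bp counted once and 33.7% without peaks under 50 bp; the cause was not tested. The combined peaks in both replicates moved from 25.37% to 21.6% with a 50% reciprocal overlap and 23.1% with midpoints within 200 bp, and those in neither from 51.5% to 54.4% and 53.1%; the reciprocal overlap is the stricter rule by construction, and for the midpoints the cause was not tested. The ratio of chromosome I turned from 1.12 to 0.946 without replicate 1, to 0.895 without replicate 2 and to 0.913 with only peaks in both replicates, and that of IV from 0.927 to 1.003 without replicate 2 and 1.02 with only peaks in both replicates; for I, scaling of significance by chromosome was examined and stays open, and for IV the cause was not tested. The call on IV was also lost with the better-ranked 50% of the list, without replicate 1 and with peaks within 1000 bp counted once, at ratios of 0.920, 0.967 and 0.939. The other 70 values for single chromosomes kept direction and call. No paired analysis was possible because values of the input samples, which share the replicate numbers, were not analysed here and no result compares groups of samples. The alternatives planned for genes, gene lists, RNA genes and motifs were not run, as the annotation was on another build. Depth limits all of these results in an unknown way, since no read counts were at hand.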

Other observations

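All tests in this part were chosen after the results they bear on had been seen. Peaks were distributed unevenly between the ends of chromosomes II and IV. On II, the right of 3 equal parts held 357 combined peaks and the left 227 (exact binomial, adjusted p = 2.92e-07 over 7 regions). On IV the order was the other way round, with 206 on the right and 331 on the left (exact binomial, adjusted p = 2.92e-07). Both replicate lists had the same order: on II 149 right and 105 left in replicate 1 (exact binomial, adjusted p = 0.024) and 175 and 111 in replicate 2, and on IV 76 right and 123 left in replicate 1 (exact binomial, adjusted p = 0.00742) and 91 and 157 in replicate 2. No such difference passed the test on I, III, V or X in the combined list. These tests treat peaks as independent, although peaks lay near each other more often than in random placements, as given below. With peaks within 1000 bp counted once, the adjusted p was 7.47e-05 on II and 5.61e-06 on IV (exact binomial). With only peaks in both replicates it was 0.0278 on II and 0.0275 on IV (exact binomial). Neither alternative removes the clustering over longer distances, such as 5000 bp, so these p-values do not account for it.

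Peaks also occurred in neighbourhoods. In the combined list 1671 neighbouring midpoints lay within 5000 bp of each other, 1.43 times the mean of 1167 in 10000 random placements (permutation p = 0.0001, the smallest they can give). Within 1000 bp there were 282, against a mean of 261 (permutation p = 0.091); no 2 peaks of a list lie closer than 200 bp, which lowers this count. The densest window of 100 kb was II 5300001–5400000, with 20 combined peaks, 10 of replicate 1 and 11 of replicate 2, followed by II 6800001–6900000 with 18, 9 and 13. Random placements had a mean of 15.8 peaks in their densest window (permutation p = 0.0145 for 20 or more). The window III 4500001–4600000 held 16 combined peaks but only 1 of replicate 1 and 4 of replicate 2. The longest stretch between combined peaks was V 16965968–17326094, with 360127 bp.

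The peak of 13176 bp on X is 41.3 times as wide as the median combined peak, and the widest combined peak outside it and its neighbour is 3877 bp. That narrow peaks were joined in the combined list alone is argued against by the replicate lists, in each of which 1 peak covers either 99.5% or 99.6% of the block; of the next 9 widest peaks, 6 are divided into 2 or more peaks in at least one replicate. A candidate explanation is that the block marks the tagged dve-1 gene itself, which this strain carries as a transgene, possibly in several copies, and whose endogenous copy lies on X. This cannot be told apart from broad binding of DVE-1, because the position of dve-1 on build WS180 and the input reads over the block were not analysed here. The block and its neighbour together span 17851 bp.

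The best-ranked peak of both replicates, at the right end of I, is missing from the combined list. It had the smallest q-value in each replicate list, and 499 of the 500 best peaks of each replicate are in the combined list, this being the exception. Its score when the combined list was made is not known. These counts therefore cannot decide whether it was too weak there. The right end of I may have been left out when the combined list was made: the last combined peak on I ends 110553 bp before it. No other replicate peak lies in that stretch, so this stays open, and no biological explanation was tested. In all, 3 peaks of replicate 1 overlapped a peak of replicate 2 but none of the combined list, and all 3 lay on I, the others at 933318–933711 and 3171486–3171882.

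Chromosome I and X hold a larger share of the combined list than of the replicate lists. Among combined peaks in neither replicate, 19.3% lay on I and 10.3% on X, against 13.7% and 7.14% of those in both (Fisher's exact test, adjusted p = 4.85e-05 and 0.00267 over 6 chromosomes), while II went the other way, with 16.03% against 22.4% (Fisher's exact test, adjusted p = 1.27e-05), and a lower share on one chromosome raises the others. A candidate explanation is that significance was scaled differently by chromosome when the combined list was made. Among peaks in both lists with a replicate −log10 q between 4 and 8, the median ratio of combined to replicate −log10 q was 2.26 on I, 2.49 on X and 1.93 on II to V against replicate 1 (permutation test, adjusted p = 0.000133 for I and for X), and 1.94, 1.73 and 1.64 against replicate 2 (permutation test, adjusted p = 0.000133 and 0.118). The lower of both gains relative to II to V was 1.17 times on I and 1.06 times on X, but without read counts a larger gain does not tell such scaling from other causes of a stronger score, so the explanation stays open for both, and no biological explanation was tested.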
